A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

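RNA libraries of 2 kinds from Saccharomyces cerevisiae BY4741 were compared, 3 of RNA assemblies and 3 of total RNA. Per the labels' protocols, RNA was isolated from log-phase yeast by phenol and chloroform extraction and ethanol precipitation, ribosomal RNA was depleted with Ribo-Zero, and paired-end libraries were made with the Illumina Nextera kit. Ribosomal RNA depletion without a step that selects poly(A) keeps transcripts without a long poly(A) tail in the libraries. Per the series' design text, assemblies formed at 150 mM NaCl, 10% polyethylene glycol, 1 mM MgCl2 and 150 µg/mL RNA and were pelleted. The labels give the same text for both groups, that extracted RNA was placed in this buffer, while the design text names total RNA only as the comparison, so how the total RNA was handled is not settled by the sources used here. Groups and replicate numbers were taken from the sample titles.

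Per the submitters' processing notes, FastQC, Trimmomatic 0.32, Bowtie 0.12.7, HTSeq and DESeq 1.22.1 were used with genome build R64. The strand setting, the treatment of reads that map to several places and the annotation are not given in the sources used here, so reads of antisense, overlapping or near-identical genes cannot be told apart. The authors deposited a signal per open reading frame and library, described per the file headers as normalised reads, together with the mean over each group. The authors also deposited a fold change, the ratio of those means, and a DESeq p-value that is listed only where it is below about 0.00995 and is otherwise replaced by text. Whether that p-value was adjusted is not given in the sources used here. The deposited signal was a read count divided by 1 size factor per library. All nonzero values (100%) in each of the 6 libraries were whole multiples of the value of 1 read within a tolerance of 0.01. The ratios of the implied size factors to median-of-ratios size factors computed from the recovered reads lay within 0.0381% of their mean. Such size factors centre the median gene, so that a fold change is relative to that gene and carries no information on the amount of RNA. The size factors were 0.821, 0.826 and 0.848 in assembly libraries and 1.32, 1.16 and 1.17 in total RNA libraries.

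The table held 6603 open reading frames, of which 40 were 0 in all libraries, and 4 lines without values. Of these identifiers, 5916 matched a RefSeq gene of build R64 and 687 did not. Chromosome positions, gene symbols and coding sequences came from RefSeq. Genes were listed as intron-containing if RefSeq gives their coding sequence in several parts. This also takes in genes whose parts are not split by an intron, such as OAZ1. All matched coding lengths (100%) were multiples of 3 and are called coding length. Near-identical genes, 221 in all, were those with a BLAST+ 2.17.0 hit of at least 95% identity over at least 50% of the coding sequence, and 40 open reading frames overlapped a non-coding gene. Depth was 8749240 to 10531980 reads per library, and the 10 most abundant genes took 14.4% to 16.8% of reads.

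As the values are not counts, the main test was limma 3.58.1 (R 4.3.3), with an empirical Bayes trend, on log2(value + 1), over the 5670 genes with a mean of at least 10, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of weakly expressed genes. All 6 libraries entered and no covariate was used. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated one, and with fry, where at least 5 members were tested, with adjustment over the 17 lists. Each list was also compared with 10000 random lists drawn from the 50 nuclear genes nearest in coding length to each member. Genes were drawn independently, so this p ignores correlation among members and the spread between libraries. Spearman's rho was computed over 5502 nuclear protein-coding genes, and partial values from ranks. Group differences of single values used an exact permutation test.

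Genes are named by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest log2 fold changes among called genes without overlap between groups and with a mean of at least 100. From each list it takes up to 3 called members with the largest change in the direction of most called members, and the called member furthest the other way. It adds the 5 longest and 5 shortest coding sequences with a mean of at least 100, and LEU2, URA3, MET17, HIS3, PMA1 and ACT1, with SCR1, RPR1, NME1 and TLC1, which were not analysed here. The tests and lists were also fixed before the data were examined.

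The limma test was checked on simulated counts for the assembly against total RNA comparison with 200 changed genes. It called 85.1% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 98.5% of those changed 4-fold, and 9 unchanged genes, among 5680 tested. All simulated libraries had the same dispersion of 0.01. In the data, the SD of a library's log2 deviations from its group mean was 0.200 to 0.283 in assemblies and 0.118 to 0.177 in total RNA. The rates therefore need not hold for these data. In the same kind of simulation camera called a planted list and 0 of 20 unchanged lists. The simulated genes varied independently, so this check cannot show how the preset correlation performs on lists of correlated genes. In the lists tested here the estimated correlation ranged from 0.0456 for translation factors to 0.896 for very long coding sequences. The count tests edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered whole reads as alternatives: edgeR called 2254 genes higher and 2448 lower, and DESeq2 2328 and 2289. Other alternatives changed the pseudocount, the filter, the scaling, the variance model, the set of genes and the libraries, or added the replicate number as a block. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 was used for the remaining steps. With 3 libraries per group, no exact permutation test can give a p below 0.1.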

Results

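RNA was extracted with phenol and chloroform from log-phase cultures of BY4741, a laboratory strain of the budding yeast Saccharomyces cerevisiae, and the RNA that condensed into assemblies in a test tube was compared with total yeast RNA. Assemblies had formed at 150 mM NaCl, 10% polyethylene glycol, 1 mM MgCl2 and 150 µg/mL total yeast RNA and were pelleted before sequencing. The data comprised 3 libraries of pelleted assemblies and 3 libraries of total RNA, all depleted of ribosomal RNA and sequenced as paired ends. Reads assigned to open reading frames numbered 8749240, 10093713 and 10531980 in assembly libraries 1, 2 and 3, and 10281076, 8948906 and 9744148 in total RNA libraries 1, 2 and 3. The measurement was the size-factor-normalised read count of each open reading frame, for 6603 open reading frames. The labels do not say that the libraries of a group came from separate cultures or separate assembly reactions, so p-values measure only the spread between these samples, which may be technical. Total RNA libraries 1 and 2 were much closer to each other than any other pair (chi-square per degree of freedom 1.57, against 12.1 to 59.8 for the other pairs within a group); this measure covers counting error only and cannot tell whether these 2 libraries share an RNA preparation. If they do, total RNA has fewer than 3 independent samples. They entered as separate libraries, as the labels list them.

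The first comparison asked which mRNAs were over- or under-represented in the assemblies relative to total RNA. The mRNAs that stood highest in the assemblies included several that encode proteins of the cell surface. PIR1, a glucan-linked cell-wall protein, had 16922 ± 3120 normalised reads in assemblies and 2989 ± 90.1 in total RNA (mean ± SD, n = 3 libraries each). UTH1, a SUN family protein, had 47674 ± 7254 against 9312 ± 405 (n = 3 each). The limma fold differences, from log2(value + 1) and not from these means, were 5.59 for PIR1 and 5.08 for UTH1. The mRNAs that stood lowest were mostly of mitochondrial origin: OLI1, which encodes a subunit of ATP synthase, had 419.5 ± 203 normalised reads in assemblies and 4494 ± 293 in total RNA (n = 3 each), and COX3, a subunit of cytochrome c oxidase, had 210.4 ± 71.3 against 2222 ± 118 (n = 3 each). PIR1 lies on chromosome XI at 141794 to 142819, UTH1 on chromosome XI at 519527 to 520624, OLI1 on the mitochondrial genome at 46723 to 46953 and COX3 on the mitochondrial genome at 79213 to 80022 (RefSeq annotation of build R64, open reading frame coordinates).

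Of 5670 genes tested with limma on log2(value + 1), 2342 were higher in assemblies, 2316 were lower and 1012 were not called at an adjusted p threshold of 0.05. A change of 2-fold or more was found for 1493 of the higher and 1465 of the lower genes, for 733 and 2250 with every library scaled to the same total, and for 650 and 680 after length and GC content were fitted out. The 5th percentile of the fold change over tested genes was 0.234 and the 95th percentile was 3.77. In 4838 genes (85.3%) the 3 assembly values lay entirely above or entirely below the 3 total RNA values, where chance gives 10%. The split between higher and lower genes rests on the size factors: with every library scaled to the same total, the median gene moved by -0.56 on the log2 scale and 1583 genes were higher and 3045 lower (34.2% of calls higher, against 50.3% with the deposited scaling). All directions below are therefore relative to the median gene.

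The 10 highest genes among those with a mean of at least 100 normalised reads and no overlap between groups were YAR068W, PRM7, FMP45, PIR1, FIG2, TIR4, PRR2, MTL1, PTR3 and UTH1, with log2 fold changes from 2.55 (SE 0.24) for YAR068W to 2.35 (SE 0.15) for UTH1. FIG2 encodes a cell-wall adhesin of mating cells, TIR4 a cell-wall mannoprotein, MTL1 a sensor of cell-wall stress, PTR3 a component of the amino acid sensor at the plasma membrane and PRR2 a protein kinase. The 10 lowest were Q0182, YGL088W, Q0297, OLI1, SCEI, ATP6, COX3, COB, RPS28B and FAU1, with log2 fold changes from -4.02 (SE 0.44) for Q0182 to -3.05 (SE 0.23) for FAU1. Assembly library 3 carried part of the change of Q0182, YGL088W and SCEI, which was -3.31, -3.38 and -2.90 without it, and without that library ATP6 was the lowest of the 10 (-3.59). Of these, YGL088W shares 216 bases with the small nucleolar RNA gene SNR10 and SCEI lies within the gene of the large mitochondrial ribosomal RNA, so their reads cannot be assigned to 1 RNA. COB overlaps the open reading frames inside its introns. FAU1 encodes an enzyme of folate metabolism and RPS28B a ribosomal protein, and both are nuclear genes. The adjusted limma p-values of these 20 genes lay between 3.17e-07 for PIR1 and 5.77e-06 for SCEI.

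**Figure D1:**
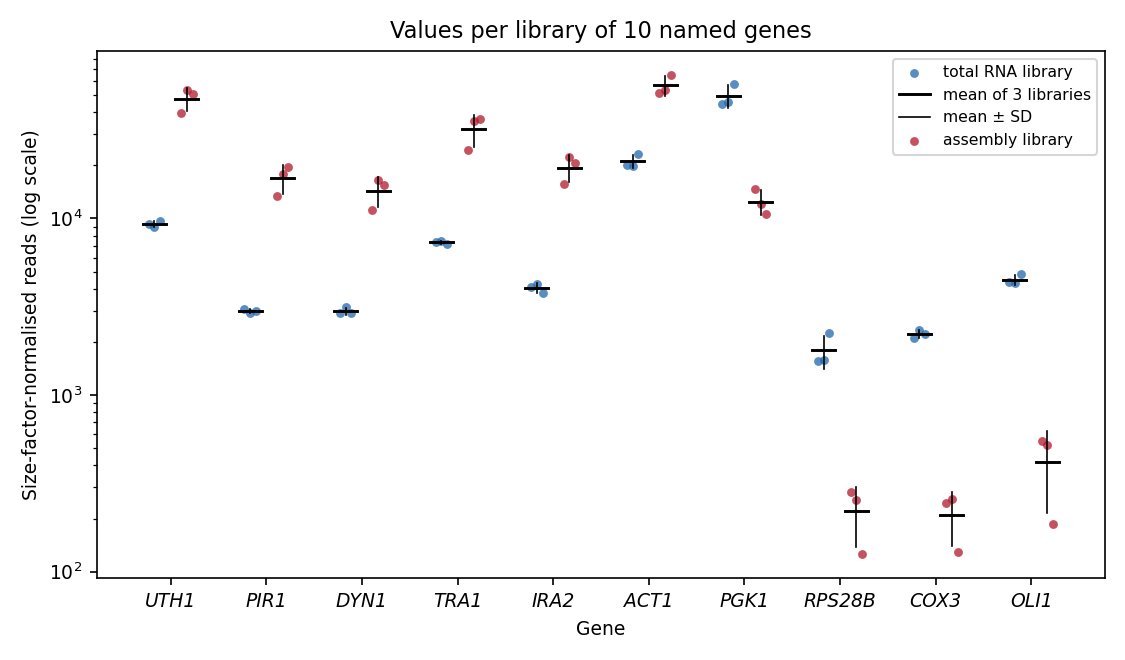
Size-factor-normalised reads (log axis) of 10 named genes in the 3 total RNA libraries (blue) and the 3 assembly libraries (red); bars give the mean and thin lines the mean ± SD of 3 libraries. In each gene the 3 assembly points lie on one side of the 3 total RNA points, above them for UTH1, PIR1, DYN1, TRA1, IRA2 and ACT1 and below them for PGK1, RPS28B, COX3 and OLI1.

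The second comparison asked how the change depended on the length of the coding sequence. The 5 genes with the longest coding sequences all rose in assemblies: REA1, a giant ATPase of ribosome assembly with 14733 nt, had a log2 fold change of 2.28 (SE 0.17), and DYN1, the dynein heavy chain (12279 nt), TRA1, a subunit of the SAGA and NuA4 acetyltransferases (11235 nt), TOM1, a ubiquitin ligase (9807 nt), and VPS13, a lipid transfer protein (9435 nt), had 2.25, 2.11, 2.11 and 2.02. Of the 5 shortest with a mean of at least 100, RPL41A and RPL41B (78 nt, ribosomal proteins), OST4 (111 nt, a subunit of oligosaccharyltransferase) and MFA1 (111 nt, the a-factor mating pheromone) fell, with log2 fold changes of -2.33, -1.69, -1.75 and -1.23, while YOR302W (78 nt, an upstream open reading frame of CPA1) rose, with 1.17 (SE 0.30). The adjusted limma p-values of these 10 genes lay between 3.17e-07 for RPL41A and 0.00329 for YOR302W, and the call of YOR302W was lost with every library scaled to the same total (adjusted p = 0.0895).

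Over 5502 nuclear protein-coding genes, Spearman's rho between the log2 fold change and coding length was 0.677 (Pearson's r with log2 length, 0.648), and it was 0.657, 0.669 and 0.680 when assembly libraries 1, 2 and 3 were each set against the mean of total RNA (mean 0.669 ± 0.0117, SD, n = 3). These correlations are across genes, which are not independent replicates. The median log2 fold change was -1.34 in 691 genes with coding sequences under 500 nt, -0.94 in 1390 genes from 500 to below 1000 nt, 0.09 in 2148 genes from 1000 to below 2000 nt (-0.47 with equal library totals), 1.25 in 1077 genes from 2000 to below 4000 nt and 1.87 in 196 genes of 4000 nt and over. In the last range 195 genes were higher and 0 were lower, and in the range under 500 nt 507 were lower and 92 higher. Within the libraries themselves, rho between the log2 value and coding length was 0.588 ± 0.0248 in assemblies and 0.345 ± 0.0107 in total RNA (SD, n = 3 each). The difference of 0.243 gave the smallest p that 3 libraries against 3 allow (exact permutation test, 2-sided, p = 0.1). The coding lengths hold no untranslated regions.

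**Figure D2:**
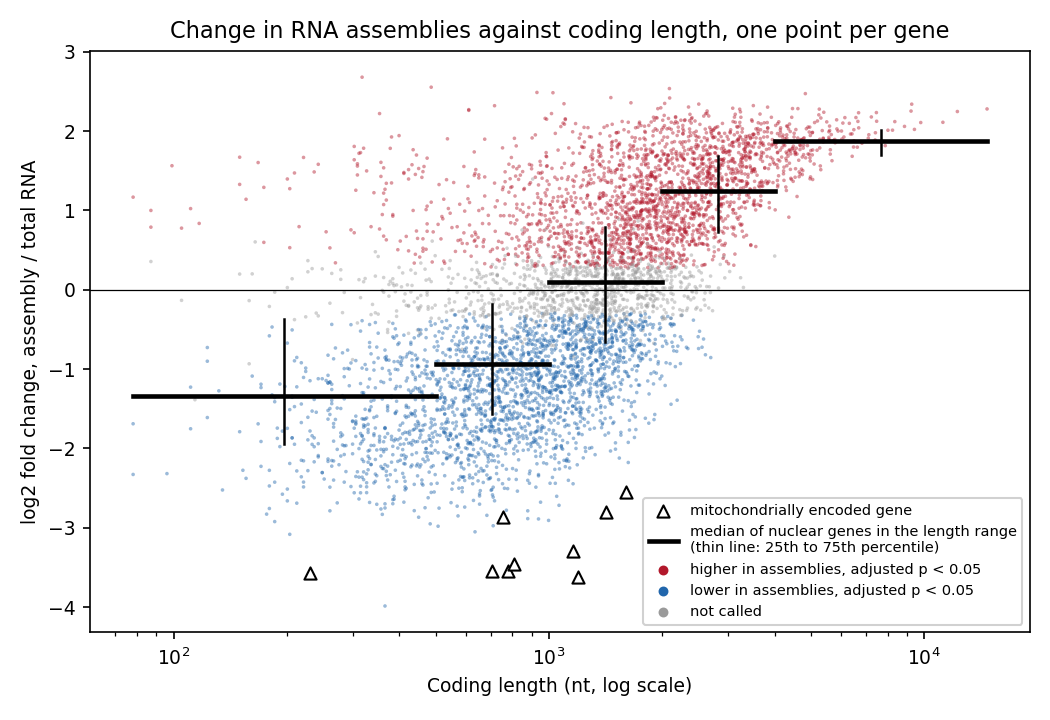
Log2 fold change (assembly over total RNA) of each tested gene with an annotated coding length against that length (nt, log axis). Red points were higher and blue points lower in assemblies at adjusted p < 0.05, grey points were not called, thick black lines give the median of nuclear genes in each length range, thin black lines the 25th to 75th percentile, and triangles mark mitochondrially encoded genes. The medians rise from -1.34 under 500 nt to 1.87 at 4000 nt and over, and the triangles lie between -3.62 (VAR1) and -2.55 (COX1).

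The base composition and the abundance of an mRNA were examined in the same way. Spearman's correlation coefficient between the log2 fold change and the GC content of the coding sequence was 0.011 over the 5502 genes, within the spread between assembly libraries (0.0112 ± 0.0136, SD, n = 3). Longer coding sequences had lower GC content (rho -0.252), and with length and mean level held constant the partial rho of GC content was 0.222. The partial rho of length with GC content and mean level held constant was 0.615. Spearman's correlation coefficient with the level in total RNA was 0.186, as the mean over the 3 ways of taking the level from 2 total RNA libraries and the fold change against the other, and the partial rho of the mean level over all 6 libraries given length and GC content was 0.089. The relation with length was weaker among weakly expressed genes: rho was 0.345, 0.602 and 0.735 among the 1834 genes with the lowest, the 1834 with intermediate and the 1834 with the highest mean level.

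Of 23 gene lists fixed before the data were examined, 17 had at least 5 members tested. Limma's camera test with a preset correlation called 14 of these 17. With the correlation estimated from the 6 libraries none of the 17 was called, the smallest adjusted p being 0.370. Limma's fry test, which asks whether the members move one way on balance and does not compare a list with other genes, called 16 of the 17, all but the chaperones. Adjusted over the list alone, the numbers of higher and lower members were the same as over all genes in every list except the respiratory chain (6 higher) and the translation factors (18 higher and 20 lower).

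Lists of large proteins stood higher in assemblies. All 55 members of the list of very long coding sequences were higher, with a median log2 fold change of 1.96 (camera, adjusted p = 1.35e-14; adjusted p = 0.370 with an estimated correlation), led by IRA1 and IRA2, the GTPase-activating proteins of Ras (2.34 and 2.25), and REA1. Of 49 genes of chromatin remodelling, Mediator and SAGA, 36 were higher and 5 lower, with a median of 1.28 (camera, adjusted p = 3.77e-05; adjusted p = 0.370 with an estimated correlation). TRA1, SNF2, the ATPase of the SWI/SNF complex, and TAF5 led with 2.11, 2.11 and 2.10, and MED4, a subunit of Mediator, was lowest (-1.46). Of 44 plasma-membrane transporters and cell-wall synthases, 32 were higher and 1 lower, with a median of 1.07 (camera, adjusted p = 3.77e-05; adjusted p = 0.396 with an estimated correlation). The potassium transporter TRK2 (2.19), the drug pump SNQ2 (1.93) and the amino acid permease GAP1 (1.89) led. The lower one was BAP3, an amino acid permease (-0.40), whose call was among those lost when a library was left out, namely without assembly library 1 (adjusted p = 0.0533), without assembly library 2 (adjusted p = 0.0543) or without total RNA library 3 (adjusted p = 0.106).

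Of 32 genes of the nuclear pore complex, 25 were higher and 3 lower, with a median of 1.03 (camera, adjusted p = 0.000185; adjusted p = 0.370 with an estimated correlation). NUP1, NUP159 and MLP2 led with 2.11, 2.09 and 1.98, and SEC13, which also serves in the COPII coat, was lowest (-1.31). Of 34 genes of the cytoskeleton and motor proteins, 24 were higher and 7 lower, with a median of 1.02 (camera, adjusted p = 0.00475; adjusted p = 0.370 with an estimated correlation). DYN1 (2.25), LAS17 (2.18) and PAN1 (2.17) led, of which LAS17 and PAN1 regulate actin assembly, and the actin-capping protein CAP1 was lowest (-2.01). This list was not called after quantile normalisation (median 0.63, adjusted p = 0.135). Of 43 genes of the small-subunit processome and ribosome biogenesis, 28 were higher and 10 lower, with a median of 1.01 (camera, adjusted p = 0.0102; adjusted p = 0.508 with an estimated correlation). REA1 (2.28), UTP20 (2.12) and KRE33 (2.06) led, and UTP6 was lowest (-1.74). This list was not called after quantile normalisation either (median 0.28, adjusted p = 0.763). After length and GC content were fitted out, camera called none of these 6 lists (adjusted p from 0.238 to 0.710), and their medians were -0.016 for very long coding sequences, 0.13 for chromatin, -0.083 for transporters, 0.15 for the nuclear pore, 0.15 for the cytoskeleton and -0.049 for the processome.

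Lists of small proteins stood lower. Of 137 genes of cytosolic ribosomal proteins, 127 were lower and 1 higher, with a median log2 fold change of -1.79 (camera, adjusted p = 1.99e-19; adjusted p = 0.370 with an estimated correlation). RPS28B (-3.08), RPS26A (-2.83) and RPL29 (-2.76) were lowest. RPS11A, which has a near-identical copy in the genome that could share its reads, was the higher one, with 0.51 (SE 0.14), and turned to -0.057 with equal library totals and -0.060 after quantile normalisation. Of 58 very short coding sequences, 51 were lower and 3 higher, with a median of -1.69 (camera, adjusted p = 9.11e-11; adjusted p = 0.370 with an estimated correlation). LSM6 (-2.79), RPL29 and RPC10 (-2.69) were lowest, and CRS5, a metallothionein, was highest (1.47). Of 263 intron-containing genes, 197 were lower and 44 higher, with a median of -1.36 (camera, adjusted p = 4.64e-10; adjusted p = 0.370 with an estimated correlation). OAZ1 (-2.88), RPL19B (-2.73) and RPL27A (-2.68) were lowest, and YLL067C, a subtelomeric helicase gene with 14 near-identical copies, was highest (2.10). OAZ1 entered this list only because its coding sequence is annotated in several parts. Its span of 458799 to 459678 leaves no room for an intron beside 879 nt of coding sequence.

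Of 39 genes of the nuclear-encoded respiratory chain and ATP synthase, 29 were lower and 5 higher, with a median of -1.34 (camera, adjusted p = 4.89e-05; adjusted p = 0.370 with an estimated correlation). COX4 (-2.75), QCR9 (-2.51) and COX9 (-2.47) were lowest, and COR1, the longest of these examples, was highest (1.37). Of 65 genes of mitochondrial ribosomal proteins, 52 were lower and 7 higher, with a median of -1.22 (camera, adjusted p = 1.16e-07; adjusted p = 0.370 with an estimated correlation). MRPL20 (-2.50), MRPL39 (-2.28) and RSM26 (-2.25) were lowest and MRPL4 was highest (1.41). Of 32 proteasome genes, 23 were lower and 4 higher, with a median of -0.89 (camera, adjusted p = 0.000932; adjusted p = 0.478 with an estimated correlation). RPN13 (-2.00), PUP3 (-1.92) and PRE3 (-1.86) were lowest, and RPN2, a large scaffold subunit, was highest (1.43). Of 10 histone genes, 8 were lower and 1 higher, with a median of -0.79 (camera, adjusted p = 0.00685; adjusted p = 0.370 with an estimated correlation). HHT1 (-2.36), HHF2 (-2.36) and HHF1 (-2.00) were lowest, of which HHF1 and HHF2 are near-identical copies that could share reads. HTB1 was higher, with 0.50 (SE 0.12), and turned to -0.062 with equal library totals and -0.036 after quantile normalisation. After length and GC content were fitted out, camera did not call the respiratory chain (median -0.41, adjusted p = 0.238), mitochondrial ribosomal proteins (-0.35, adjusted p = 0.0733), the proteasome (-0.44, adjusted p = 0.0733) or the histones (0.21, adjusted p = 0.710), and it called cytosolic ribosomal proteins (-0.78), very short coding sequences (-0.56) and intron-containing genes (-0.44) lower. Those calls are at the preset correlation, and an estimated correlation was not used with this correction.

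The remaining 3 lists were not called. Of 20 genes of glycolysis and fermentation, 9 were higher and 5 lower, with a median of 0.05 (camera, adjusted p = 0.628). PYK2 (1.81), PFK1 (1.73) and PFK2 (1.59) were highest, and PGK1, phosphoglycerate kinase, fell from 49487 ± 7477 to 12467 ± 1998 normalised reads (n = 3 each; limma log2 fold change -1.99). The call of PFK1 was lost after length and GC content were fitted out (0.17, limma, adjusted p = 0.0759). That of PFK2 was lost when the replicate block was added to this correction (0.22, adjusted p = 0.0995). Of 33 chaperone genes, 13 were higher and 13 lower (camera, adjusted p = 0.936), and their median (0.04) and mean (-0.095) differed in sign. SSA3 (1.51), HSP104 (1.44) and STI1 (1.15) were highest and HSP10 was lowest (-2.30), and the calls of HSP104 (0.029) and STI1 (0.43) were lost after length and GC content were fitted out, that of STI1 only without the replicate block. The median of this list was -0.21 in assembly library 3 against 0.33 and 0.40 in libraries 1 and 2, and after quantile normalisation the list was called lower (median -0.48, adjusted p = 0.0186). It was also called lower with the replicate block after length and GC content were fitted out (camera, median -0.41, adjusted p = 0.0264). Of 40 translation factors, 17 were higher and 19 lower (camera, adjusted p = 0.936), and their median (-0.088) and mean (0.032) differed in sign. SUI1 (-2.43), EFB1 (-1.79) and TIF11 (-1.51) were lowest, with EFB1 overlapping the small nucleolar RNA gene SNR18, and GCN1, an activator of the Gcn2 kinase, was highest (2.01). After quantile normalisation this list was called lower (median -0.55, adjusted p = 0.0344). With length and GC content fitted out, the calls of GCN1 (-0.085, limma, adjusted p = 0.317) and TIF11 (-0.20, adjusted p = 0.273) were lost.

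**Figure D3:**
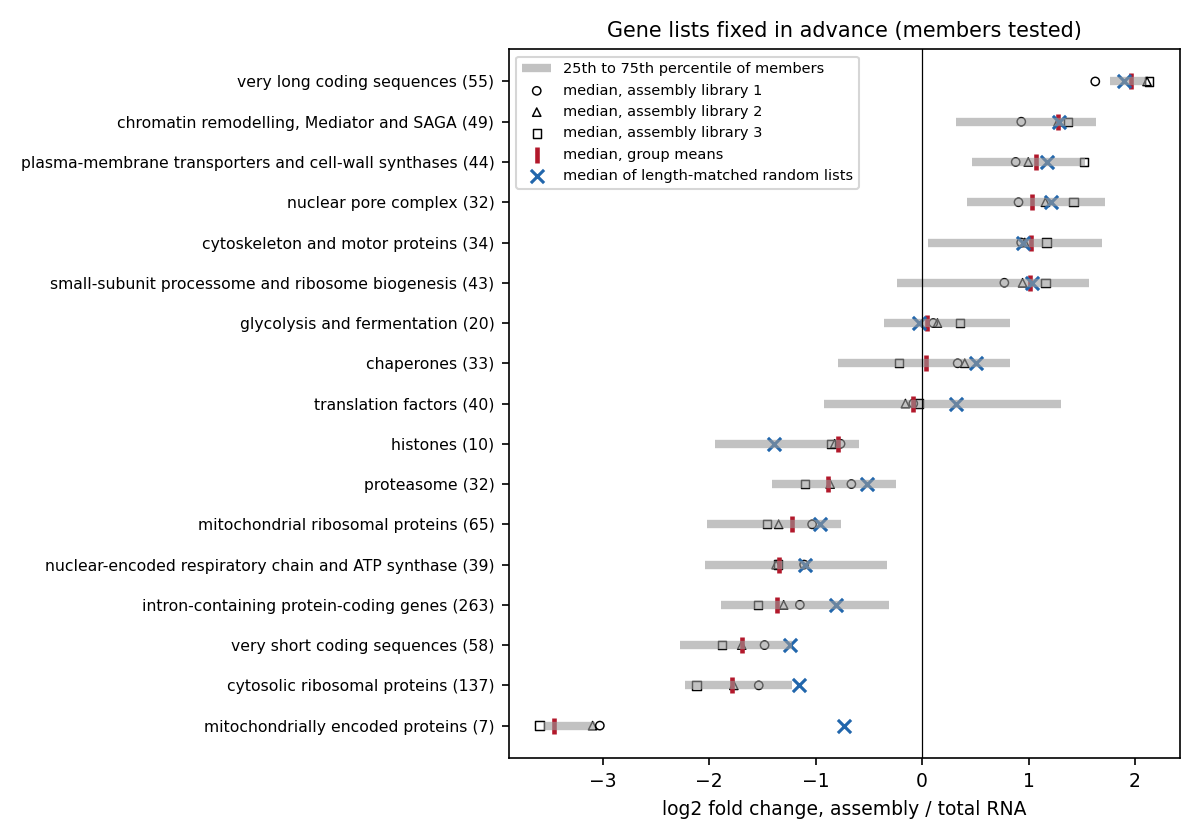
Median log2 fold change (assembly over total RNA) of the 17 gene lists tested, with the number of members tested in parentheses. Red ticks give the median on group means, open symbols the medians of the 3 assembly libraries each against the mean of total RNA, grey bars the 25th to 75th percentile of members, and blue crosses the median of 10000 lists of nuclear genes matched on coding length; the cytosolic ribosomal proteins (-1.79) and the mitochondrially encoded proteins (-3.46) lie below their crosses at -1.16 and -0.73.

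Since the lists differ in coding length, each was also set against 10000 random lists of nuclear genes matched on length. After adjustment over 17 lists, 4 passed the threshold (length-matched resampling), of which 3 had medians apart from those of genes of their length. The resampling drew genes independently, so its p-values ignore correlation among members and the spread between libraries. Camera with an estimated correlation, which does not match on length, called none of the 17 lists (smallest adjusted p 0.370). Cytosolic ribosomal protein genes had a median of -1.79 against -1.16 in matched lists (adjusted p = 0.00113), intron-containing genes -1.36 against -0.81 (adjusted p = 0.00113), mitochondrially encoded genes -3.46 against -0.73 (length-matched resampling, adjusted p = 0.00113), each with the smallest p that 10000 draws allow before adjustment. The other was the list of very long coding sequences (1.96 against 1.89, adjusted p = 0.0229), whose longest members have few genes as long to be matched with, and which was not called after length and GC content were fitted out (median -0.016, adjusted p = 0.710), so no difference from genes of its length is read from it. The 13 others did not pass, among them the nuclear pore complex (1.03 against 1.21), Mediator and SAGA (1.28 against 1.29), the transporters (1.07 against 1.18) and the proteasome (-0.89 against -0.52).

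The mitochondrially encoded mRNAs were examined as a class of RNA. All 11 mitochondrially encoded open reading frames tested were lower in assemblies, with a median log2 fold change of -3.54, against 0.013 for 5502 nuclear protein-coding genes. The 11 include SCEI, which lies within the gene of the large mitochondrial ribosomal RNA, and Q0182 and Q0297, which have no RefSeq coding length. Not all of the 11 can therefore be read as mRNAs. Among the 7 tested members of the list of mitochondrially encoded proteins, all 7 were lower, with a median of -3.46 (camera, adjusted p = 0.000261; adjusted p = 0.370 with an estimated correlation). VAR1, a mitochondrial ribosomal protein (-3.62), OLI1 (-3.57) and ATP6 (-3.54) were lowest. The median of these 7 was -3.03, -3.10 and -3.59 in assembly libraries 1, 2 and 3. The 157 tested open reading frames that RefSeq does not annotate as protein-coding had 60 higher and 45 lower members and a median of 0.30, which turned to -0.26 with equal library totals. Small nucleolar RNAs, spliceosomal RNAs, transfer RNAs, ribosomal RNAs, other structured non-coding RNAs and Ty elements had no rows in the table of open reading frames, and these 6 lists were not analysed here; nor were SCR1, RPR1, NME1 and TLC1.

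Several genes had been chosen for report whatever their values. ACT1, which encodes actin, rose from 21058 ± 1771 to 56665 ± 7450 normalised reads (n = 3 each; limma log2 fold change 1.42, SE 0.15, adjusted p = 3.12e-06). PMA1, the plasma-membrane proton pump, had 71594 ± 4521 in total RNA and 124040 ± 27647 in assemblies (n = 3 each; limma log2 fold change 0.77, SE 0.18, adjusted p = 0.00166), and its call was lost with equal library totals (adjusted p = 0.226) and after quantile normalisation (adjusted p = 0.323), while after length and GC content were fitted out it was called lower (-0.66, adjusted p = 0.00358). BY4741 lacks LEU2, URA3 and MET17 and carries a partial deletion of HIS3. LEU2 and MET17 had 0 reads in all 6 libraries, which allows a share of up to 3.43e-05% of reads in the shallowest library (counting error only), and URA3 had 1 read in total RNA library 2 and 0 in the others. HIS3 had between 131 and 344 reads per library and a log2 fold change of -0.48 (limma, SE 0.15, adjusted p = 0.0125). That call was lost after quantile normalisation (-0.070, adjusted p = 0.674), after length and GC content were fitted out without the replicate block (-0.29, adjusted p = 0.0984), with limma's treat test against a 1.2-fold change (adjusted p = 0.123), without assembly library 2 (-0.40, adjusted p = 0.0546) and without total RNA library 3 (-0.36, adjusted p = 0.0683).

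In the authors' deposited table, 3948 open reading frames carried a p-value, the largest of them 0.00995, and 2650 were marked NS. Of those listed, the authors' deposited table gave 1980 a fold change above 1 and 1968 a fold change below 1. Of the 3917 listed genes that were tested here, 1971 were higher and 1946 were lower in the limma test, matching the direction in the authors' deposited table in each case. The limma test called 741 genes that carry no p-value in the authors' deposited table.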

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

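Alternatives chosen after seeing the data were the correction for length and GC content without a block, total RNA libraries 1 and 2 averaged as 1, and the removal of overlapping and near-identical genes; the others were planned. Over 25 alternatives to the gene test, the numbers of higher and lower genes stayed within 1.5 times of 2342 and 2316, and leaving out 1 library gave 2194 to 2344 higher and 2190 to 2349 lower genes. Averaging total RNA libraries 1 and 2 gave 2207 higher and 2206 lower genes. Of 91 named genes, 70 kept their direction and their side of the threshold under all alternatives to the gene test that were run for them. Of 17 lists, 5 did so under those alternatives with camera at its preset correlation, but none of the 14 lists it called was called with an estimated correlation. The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05; the real split gave 2342 higher, 2316 lower, 1493 higher by 2-fold and 1465 lower by 2-fold, and the highest of the others gave 0 in each, so 1 split reached each count. No alternative changed the depth; without the filter on low values 2388 genes were higher and 2452 lower, and with a mean of at least 50 these were 2240 and 2107.

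Same-numbered libraries of the 2 groups had correlations of their deviations from the group means of 0.078, 0.167 and 0.276. Assembly libraries 1 and 3 correlated best with their own number, and assembly library 2 with total RNA library 1 (0.220). Total RNA libraries 1 and 2 were much alike, so these values cannot decide whether the numbers pair the libraries. The labels do not say so, and the main test used no pairing. With the replicate number as a block, 2375 genes were higher and 2350 lower, 1495 and 1466 of them by 2-fold or more, and 14 lists were called.

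Equal library totals moved the median gene by -0.56, and the genes changed 2-fold or more became 733 higher and 2250 lower. Under that scaling the log2 fold changes of RPS11A and HTB1 became -0.057 and -0.062, and the medians became -0.47 for coding sequences of 1000 to below 2000 nt, -0.43 for aminoacyl-tRNA synthetases, -0.10 for the ubiquitin pathway and -0.26 for open reading frames outside RefSeq, which follows from the shift. After quantile normalisation RPS11A, HTB1 and the median of the chaperones became -0.060, -0.036 and -0.48, and rho with length and with GC content was 0.538 and -0.023; the cause was not tested.

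Fitting length and GC content out of each library removes the length relation by construction (rho 0.072). It left 650 genes higher and 680 lower by 2-fold or more and 3 lists called, or 655, 682 and 4 with the replicate block, under which the chaperones were called lower (camera, adjusted p = 0.0264). With both fitted out together, so that neither is singled out, several values changed sign. The medians became 0.21 for histones, -0.083 for the transporters, -0.049 for the processome, -0.016 for very long coding sequences and -0.41 for the chaperones. They became -0.0023 for 1000 to below 2000 nt, -0.20 for helicases and -0.42 for aminoacyl-tRNA synthetases. Those of the ubiquitin pathway and phosphatases became -0.056 and 0.00097. GCN1, VPS13 and PMA1 had -0.085, -0.055 and -0.66, of which PMA1 was called lower (limma, adjusted p = 0.00358). The calls of HSP104 (0.029), STI1 (0.43), TRA1 (0.075), SNF2 (0.14), DYN1 (0.25), PFK1 (0.17), SNQ2 (0.0060), RPN2 (0.031), TIF11 (-0.20), IRA2 (0.18), TOM1 (0.041) and HIS3 (-0.29) were lost without the block. With the block, those of PFK2 (0.22) and NUP159 (0.20) were lost as well, and those of STI1 and HIS3 were not. The correction gave no value for the list of mitochondrially encoded proteins. Set against length-matched random genes, 4 lists were called, and with an estimated correlation camera called 0 of 17 lists, while fry called 16 and camera's smallest adjusted p was 0.370.

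Spearman's correlation coefficient with length was 0.637 without a filter, 0.702 with a mean of at least 50, 0.633 with DESeq2 fold changes and 0.689 without overlapping and near-identical genes; the cause was not tested. Spearman's correlation coefficient with GC content was -0.0057 with a mean of at least 50 and 0.043 without cytosolic ribosomal protein genes. Spearman's correlation coefficient with the level in total RNA was 0.196 without a filter, 0.172 with a mean of at least 50, 0.227 without overlapping and near-identical genes, 0.250 without cytosolic ribosomal protein genes, and 0.176 to 0.202 when 1 library was left out.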

Other observations

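The tests of gene families named by annotation words, of C content and of cell-wall genes were chosen after results had been seen. So were the tests of mitochondrial genes within and below the nuclear range of GC content. The comparison of each library's own relation with length was planned, but its use to weigh RNA integrity and pelleting was chosen afterwards. Genes whose RefSeq annotation mentions the cell wall or a GPI anchor stood high in the assemblies: of 203 tested, 128 were higher, 40 lower and 35 not called, with a median log2 fold change of 0.93, against 0.12 in length-matched lists (adjusted p = 0.0011 over 11 families, length-matched resampling). Their medians in assembly libraries 1, 2 and 3 were 0.81, 0.94 and 0.97. For these families too, the resampling took genes as independent of each other. Examples chosen after their values were seen are CCW14 (2.32, SE 0.14), SED1 (2.22, SE 0.17) and DSE2 (2.16, SE 0.14), cell-wall proteins all, while END3, an endocytosis gene matched by the same words, was lowest (-2.60). The 38 aminoacyl-tRNA synthetase genes stood lower than other genes of their length: 14 were higher and 13 lower, with a median of 0.14 (-0.43 with equal library totals) against 0.66 in matched lists (adjusted p = 0.0233). Subunits of the vacuolar ATPase had 12 lower and 3 higher members of 15, with VMA3 lowest (-2.95) and STV1 highest (1.54), and their median of -1.11 did not pass against matched lists (-0.46, adjusted p = 0.168).

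The lower level of intron-containing genes was not confined to ribosomal protein genes. The 174 genes listed as intron-containing that encode no cytosolic ribosomal protein had a median of -0.95 against -0.60 in matched lists (adjusted p = 0.00825). The lowest of them, OAZ1 (-2.88), has no intron and was not removed. Ribosomal protein genes with an intron (89) and without (48) had medians of -1.77 and -1.79, against -1.18 and -1.14 in matched lists (adjusted p = 0.0011 and 0.0022). Protein kinases (median 0.99, 127 tested, adjusted p = 0.139), helicases (0.90, 56 tested, adjusted p = 0.0645), the ubiquitin pathway (0.47, or -0.10 with equal library totals, 103 tested, adjusted p = 0.938), phosphatases (-0.18, 119 tested, adjusted p = 0.938) and cyclins (-0.071, 20 tested, adjusted p = 0.988) did not pass the same test.

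Among nuclear genes, what length and level left over rose with the share of C in the coding sequence. Length explained 47.3% of the variance of the log2 fold change, length and level 48.5%, and length, level and base fractions 58.9%. Spearman's rho of the remainder with the C fraction was 0.380 over 5502 genes (0.371, 0.372 and 0.371 in the 3 assembly libraries), while it was -0.143 with the G fraction, -0.083 with A and -0.146 with T. The fifth of genes poorest in C had a median remainder of -0.40 and the fifth richest in C had 0.67. The relation was 0.433 among 1631 genes with a mean of at least 1000, 0.404 without cytosolic ribosomal protein genes, and 0.266, 0.262 and 0.193 for C at codon positions 1, 2 and 3.

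The rise with coding length was weighed against 3 technical explanations. For counting noise of short or weakly expressed genes, rho was taken among genes with a mean of at least 1000, where it was 0.736. Such noise scatters values both ways and weakens a correlation, so a high value there was likely in any case. The value shows only that the rise held among well-measured genes. Base composition would remove it once the base fractions were held constant, but the partial rho was 0.692. RNA integrity that differs between the groups, or pelleting that depends on size, could give a difference of 0.243 between the groups' own rho with length, as could a preference of assemblies for long RNA, and these cannot be told apart because each follows the groups in a table of reads per gene. Coverage along transcripts was not analysed here.

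The low level of mitochondrially encoded mRNAs in the assemblies was weighed against 2 technical explanations. Short coding sequences would place their median of -3.46 within that of length-matched nuclear lists, whose 2.5th percentile was -1.54. Low GC content was not decided by the 550 nuclear genes with the lowest GC content (median log2 fold change -0.13), since their median GC content of 35.3% lies above the 10.4% to 33.3% of the mitochondrial genes. The 46 nuclear genes at or below 33.3% had a median of -0.85. The 5 mitochondrial genes within the nuclear range of GC content had a median of -3.30, below the 2.5th percentile of -1.61 in lists of nuclear genes nearest in GC content (26.3% to 33.6%), which argues against GC content alone for these 5. Those lists drew on only 42 nuclear genes, and length and GC content were not matched together. For the other 2, ATP6 and VAR1, with a median of -3.58, low GC content cannot be told apart from their origin because no nuclear gene has as low a GC content, and other features of mitochondrial mRNAs were not tested.

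The high level of cell-wall and GPI-anchored protein genes was weighed against 2 technical explanations. Reads shared with overlapping or near-identical genes would end it once those genes were left out, but the median remainder after length and level was then 0.936 of that with them (95% bootstrap interval 0.523 to 1.58). This left 195 of the 203 genes, so the median could move little. The value shows only that these 195 stood high without such overlaps or copies, and genes alike below 95% identity stayed in. Base composition remains open as a candidate explanation: after the base fractions were also fitted, 0.475 of the median remainder was left, with an interval of 0.168 to 0.808 that spans both a minor and a major share. Whether the encoded proteins have any part in it was not tested.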
